A study of Mus musculus with 22 samples.

How the data were processed

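Gene expression was measured by RNA sequencing in intestinal tissue of male C57BL/6 mice, an inbred laboratory strain, that entered the experiment at 7 weeks of age. Per the labels' protocols, the animals ate for 7 weeks a diet with 8% fibre by weight, with 35% of the energy from fat, 20% from protein and 45% from carbohydrate. The fibre was cellulose (a poorly fermented fibre, here the control), inulin (a fermentable fructan) or pectin (a fermentable galacturonan). Exposed groups also received PFOS (perfluorooctanesulfonic acid, a persistent fluorinated surfactant) in the drinking water at 3 µg per kg body weight per day. Total RNA was extracted on silica columns, its integrity was examined on a Fragment Analyzer, and strand-specific libraries were sequenced on a BGI DNBSEQ instrument, per the labels. The gut segment, the read length and the program that counted reads are not given in the sources used here. A treatment field of every sample mentions PFOS, so exposure was taken from the group name in the sample titles: Control (n = 4), PFOS (n = 4), Inulin (n = 3), Inulin_PFOS (n = 3), Pectin (n = 4) and Pectin_PFOS (n = 4). The titles number the biological replicates of a group. Nothing states outright that each is a separate animal, so a p-value measures the spread between these samples.

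The authors deposited, for each sample, an estimated (expected) count and a TPM value (transcripts per 1000000) per gene. The submitters' processing notes name HISAT, Bowtie2 and the mouse build GRCm39, with no version or role. Gene coordinates in the deposited tables nevertheless match the older build: of 46005 genes shared with the GENCODE M21 annotation of GRCm38, 38860 have an identical start and end, and every coordinate printed here is on GRCm38. The deposited tables hold 46603 genes, 43142 of them with a symbol. Between 3.8% and 4.8% of a library's gene values were fractional, and the deposited expected counts were rounded to whole numbers before testing. How the authors divided reads between similar genes is not stated, so members of families with near-identical copies are named as uncertain, as are genes that overlap a neighbour.

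Differential expression was tested on the rounded counts with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. The library scaling was TMM (trimmed mean of M values), low genes were removed with the default expression filter, and 15763 genes were tested. A single model with a mean per group was fitted to the 22 libraries, which shared the estimate of spread (common dispersion 0.102, a biological coefficient of variation of 31.9%). P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05. The 10 comparisons were 7 pairs of groups, the interaction of PFOS with inulin and with pectin (the PFOS effect on that fibre minus the PFOS effect on cellulose), and the PFOS effect averaged over 3 diets. Expression levels are counts per 1000000 (CPM) after TMM scaling, as mean ± SD over the group's libraries. Log2 fold changes are given ± a standard error (SE), taken as the absolute log2 fold change divided by the square root of F. Log2 CPM values were computed with a prior count of 2. Principal components were computed on the 2000 most variable genes. A gene was counted as detected in a library from 10 counts on.

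Before the data were examined, 39 gene lists were fixed (metabolic and nuclear receptor pathways, defence and stress responses, and markers of intestinal cell types, gut segments and neighbouring tissues), with 605 entries of which 603 were found in the tables. So were the groups, the model, the alternatives and the rule for naming genes. Each list was tested with camera of limma 3.58.1, a competitive test of the list against all other genes, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Fry, the rotation test of limma for a list moving on balance in one direction, was run beside it. Members are also counted with p-values adjusted over the list alone. Some lists share members, such as Lyz1, Itln1 and Ang4 in the defence and Paneth cell lists and Fabp6 and Slc10a2 in the bile acid and ileum lists. Results of such lists are not independent. Functional term annotations were not used here. A list score is the mean log2 CPM of the members, centred on the mean over the libraries.

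The rule named, per comparison, up to 10 higher and 10 lower genes with the largest change among those with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups, leaving out predicted gene models. It added up to 4 passing members of each list by p, then a few fixed genes (here Cpt1a, Pdk4 and Angptl4) in every PFOS comparison, and the 5 genes with the smallest p where fewer than 5 passed. Some genes the rule named are not reported here. The narrowing of the others to the ones in the text, and the counts of immunoglobulin variable segments, were chosen after their values had been seen.

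Alternatives to the main analysis were the size factors of DESeq2 1.42.0, no filter on low counts, the DESeq2 Wald test, a model of the compared groups alone, a replicate number as a block, limma on the deposited TPM as log2(TPM + 1) or log2(TPM + 0.1) with and without a filter, 1 surrogate variable from sva 3.50.0, and each library left out in turn. Removal of each library's GC trend, scaling by library totals alone, the omission of Pectin_PFOS replicate 1 from comparisons it is no part of, and the list tests without each library were added after the data had been seen. DESeq2's adjusted p was left missing where the program gave none.

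Library totals were 17613297 to 20261357 counts. The model was tested on simulated counts for the same 15763 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 34 and 73 of them for PFOS vs Control, 31 and 79 for Inulin vs Control, 30 and 81 for Pectin vs Control, 20 and 68 for Inulin_PFOS vs Inulin, and 41 and 72 for Pectin_PFOS vs Pectin. For Inulin_PFOS vs PFOS it recovered 28 and 75, for Pectin_PFOS vs PFOS 34 and 77, for the interaction with inulin 6 and 42, for the interaction with pectin 9 and 64, and for the averaged effect 67 and 96. False calls numbered between 1 and 10 per comparison. Scores and shares of signs were compared with two-sided exact permutation tests. Single libraries that stood apart in groups of 4 were flagged with Dixon's Q test on the CPM of named genes and on library measures.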

Results

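The experiment crossed exposure to PFOS with the kind of dietary fibre, and 22 intestinal libraries were compared in 6 groups. Control and PFOS (cellulose), Pectin and Pectin_PFOS held 4 libraries each, and Inulin and Inulin_PFOS 3 each. Library totals lay between 17613297 and 20261357 counts. Mitochondrial genes took 2.85% to 14.9% of a library's counts. Their share ranged most widely in Control (3.74% to 14.9%) and was lowest in Pectin_PFOS (2.85% to 3.51%). Pectin_PFOS replicate 1 stood apart, with the fewest detected genes (12927), the smallest scaling factor (0.749) and an extreme value of 58.5 on the second principal component, which held 17.3% of the variance. No pair of libraries agreed within counting error, the closest being Pectin_PFOS replicates 3 and 4 (chi-square per degree of freedom 29.5).

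Changes below are relative to TMM scaling. Scaled by library totals alone, the median log2 fold change of all genes was −0.41 for Pectin_PFOS vs PFOS, −0.33 for Inulin_PFOS vs PFOS and −0.27 for Pectin_PFOS vs Pectin. It was −0.20 for Inulin vs Control, −0.15 for Pectin vs Control and −0.30 for the interaction with pectin. No named gene that passed changed sign under that scaling. Camera with its preset correlation called 6 to 21 of the 39 gene lists per comparison. With an estimated correlation it called only the defence genes in Inulin_PFOS vs PFOS and the stress response genes in Pectin_PFOS vs PFOS, and each of these calls was lost without some single libraries. Fry called 0 lists for PFOS vs Control, Inulin vs Control and the averaged effect, and 1 to 11 in the other comparisons. Markers of the proximal small intestine, ileum and colon were not called in any comparison (smallest adjusted p 0.12, 0.085 and 0.28). Nor were fatty acid synthesis, bile acid handling, aryl hydrocarbon receptor, adipocyte and exocrine pancreas lists (smallest adjusted p 0.32, 0.27, 0.11, 0.05 and 0.09). The proximal small intestine score ranged from −0.88 to 1.77 in PFOS, −0.99 to 1.36 in Pectin and −0.31 to 1.65 in Pectin_PFOS, and less in the other groups. With such a spread, the missing calls do not show an equal position along the gut.

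**Figure D1:**
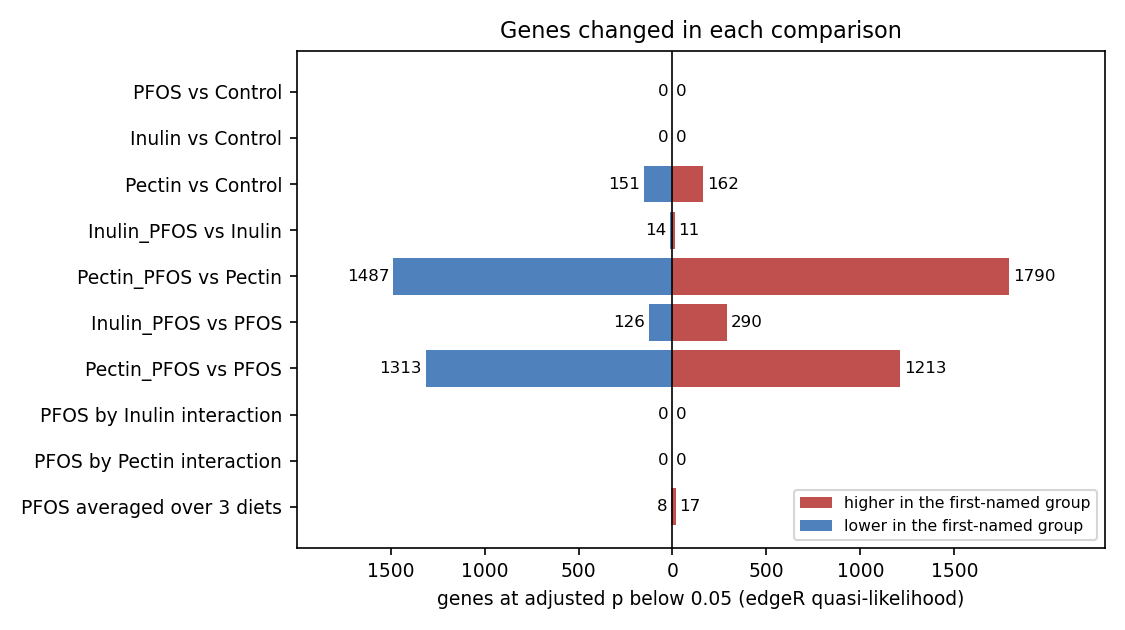
Number of genes with an adjusted p under 0.05 on the horizontal axis for each of the 10 comparisons on the vertical axis, with bars for higher genes to the right and for lower genes to the left of 0. Pectin_PFOS vs Pectin had 1790 higher and 1487 lower genes, and PFOS vs Control had 0 of either.

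PFOS vs Control addressed the effect of PFOS on the cellulose diet, and no gene passed. Id1, an inhibitor of differentiation and a BMP target, had 73.8 ± 20.1 CPM in Control and 149 ± 51.8 CPM in PFOS (SD, n = 4 each; log2 fold change 1.01 ± 0.24, adjusted p = 0.822). The fatty acid oxidation gene Cpt1a (−0.10 ± 0.28), the lipase inhibitor gene Angptl4 (−0.18 ± 0.42) and Pdk4 (0.42 ± 0.45) differed by less than their standard error. edgeR called 0 of 15763 genes, with 842 at an unadjusted p under 0.05. The DESeq2 Wald test called 1, and limma on TPM called 0 with a filter and 7 without.

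Several gene groups leaned one way. Among markers of Paneth cells, the antimicrobial cells of the crypt base, 10 of 11 had a negative fold change (median −0.86). None passed over all genes, and 3 were lower adjusted over the list alone. The list test gave adjusted p = 5.7e-05, and adjusted p = 0.66 with an estimated correlation. Antimicrobial and epithelial defence genes, a list that shares members with the Paneth cell list, were negative in 20 of 24 members (median −0.46). Smooth muscle markers were negative in 12 of 12 (median −0.74). In neither list did a member pass over all genes or adjusted over the list alone. Both lists had adjusted p = 0.0024, and adjusted p = 0.66 and 0.92 with an estimated correlation. Immediate early genes were positive in 12 of 13 members (median 0.27, adjusted p = 0.00039) and clock genes in 13 of 17 (median 0.31, adjusted p = 0.01). Neither call held (adjusted p = 0.66 for both with an estimated correlation). Ketone body genes had a median of −0.28 over 6 members, with 1 lower adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation). Single libraries decided each of these 6 calls in camera. Without Control 4 the Paneth cell (median −0.36, adjusted p = 0.054) and defence calls (−0.22, 0.098) were lost, and without Control 2 the muscle (−0.09, 0.64) and ketone body calls (−0.27, 0.051). Without PFOS 2 the clock (0.13, 0.49), immediate early (0.14, 0.079) and ketone body calls (−0.17, 0.06) were lost, and without Control 3 the clock call (0.20, 0.076). Kept calls had medians of −0.70 for defence genes without PFOS 3, 0.43 for immediate early genes without Control 2 and −0.15 for ketone body genes without Control 4.

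Inulin vs Control isolated the fermentable fructan without PFOS. The 5 genes with the smallest p all missed the threshold (adjusted p = 0.0652). Id1 had 198 ± 34 CPM in Inulin (n = 3) and 73.8 ± 20.1 CPM in Control (n = 4), a log2 fold change of 1.42 ± 0.25. Rnd3, a regulator of the cytoskeleton, was at 0.91 ± 0.18, the oxysterol hydroxylase gene Cyp7b1 at −2.37 ± 0.46 and the stromal gene Islr at −1.60 ± 0.31. edgeR called 0 genes, with 3257 at an unadjusted p under 0.05, and the DESeq2 Wald test called 783 (192 higher, 591 lower). Single libraries decided the count, which was 794 without Control replicate 1 (244 higher, 550 lower), 275 without Pectin_PFOS replicate 1, 117 without Inulin replicate 3 and 1 without Inulin replicate 1.

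Fibroblast, muscle and nerve markers leaned down in Inulin. All 12 fibroblast markers had negative fold changes (median −1.30), and 11 were lower adjusted over the list alone against 0 over all genes. Their list test gave adjusted p = 6.6e-08, and adjusted p = 0.59 with an estimated correlation. Of 12 muscle and 12 enteric nerve markers, 8 each were lower adjusted over the list alone (medians −1.17 and −1.51, adjusted p = 1.6e-05 and 6.2e-05). With an estimated correlation these had adjusted p = 0.79 and 0.59. Paneth cell markers were lower in 10 of 11 adjusted over the list alone (median −1.39, adjusted p = 2.3e-06, and adjusted p = 0.59 with an estimated correlation). All 25 cholesterol synthesis genes had positive fold changes (median 0.42), and none passed over all genes or adjusted over the list alone. That list had adjusted p = 0.00044, and adjusted p = 0.87 with an estimated correlation. Immediate early (median 0.68), enterocyte (0.50), T cell (0.47), tight junction (0.34), stress response (0.33), lipid absorption (0.29) and PPAR-alpha target genes (0.18) were also called up, and Wnt and stem cell genes down (−0.50). These 8 lists had adjusted p between 0.59 and 0.90 with an estimated correlation, and the PPAR-alpha median turned negative under library totals alone.

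Fibroblast, nerve, muscle, Paneth cell, enterocyte and immediate early lists kept their calls for Inulin vs Control in each omission of a library. The muscle median was −0.66 without Control 2 and −1.77 without Inulin 2, that of Paneth cells −0.90 without Control 4 and that of enterocytes 0.32 without Inulin 1. Camera lost the cholesterol synthesis call without Inulin 2 (median 0.27, adjusted p = 0.054), and that median was 0.22 without Control 4 and 0.68 without Inulin 3. Stress response genes lost theirs without Inulin 2 (0.082) and had a median of 0.21 without Control 4. For Wnt genes the call was lost without Control 1 (−0.30, 0.13) or Inulin 1 (−0.24, 0.094), with −0.78 without Control 2 and −0.88 without Inulin 3. T cell markers lost theirs without Control 1, 2 or 4, Inulin 2 or 3 or Pectin_PFOS 4 (up to 0.56). Their median was 0.13, 1.35 and 0.23 without Control 2, 3 and 4 and 0.75 and 0.15 without Inulin 1 and 3. PPAR-alpha genes lost theirs without Control 4 (0.11) or Inulin 1 (0.04, 0.23), with 0.36 without Control 1 and 0.34 without Inulin 2. The tight junction call was lost without Control 1, 3 or 4 or Inulin 1 (up to 0.2). That of lipid absorption was lost without Control 1 or 4, Inulin 1 or 3, any 1 PFOS library or Pectin_PFOS 1 or 4 (up to 0.26), and its median was 0.44 without Inulin 2.

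Pectin vs Control isolated the pectin diet without PFOS, and edgeR called 162 genes higher and 151 lower. Igha, the constant region of immunoglobulin A (chromosome 12, 113254830 to 113260236), went from 146 ± 28.4 to 1660 ± 948 CPM (SD, n = 4 each; log2 fold change 3.51 ± 0.58, adjusted p = 0.00904). Zbp1, an interferon-induced sensor of nucleic acids, rose from 7.52 ± 3.33 to 64.5 ± 26 CPM (3.10 ± 0.54, adjusted p = 0.0128). Duox2, the epithelial oxidase that releases hydrogen peroxide into the lumen (chromosome 2, 122279247 to 122298165), rose from 70.7 ± 22.3 to 313 ± 157 CPM (2.15 ± 0.45, adjusted p = 0.0266). Bmp1, a procollagen-processing protease (chromosome 14, 70474557 to 70520260), fell from 93.6 ± 22.7 to 20 ± 1.22 CPM (−2.23 ± 0.33, adjusted p = 0.00594). The transporter genes Abcc6 (−2.04 ± 0.37) and Abcc5 (−1.83 ± 0.34) also fell. Gsr, which regenerates reduced glutathione (1.35 ± 0.23), Asns, an asparagine synthetase induced by amino acid shortage (1.41 ± 0.26), and the gut hormone gene Cck (1.75 ± 0.31) rose, with adjusted p from 0.00904 to 0.0147.

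Among these 313 genes, 10 of 109 immunoglobulin variable segments were higher. Defence genes were positive in 22 of 24 members (median 1.31). Over all genes 4 rose (Duoxa2, Duox2, Reg3a and Lypd8) and 0 fell, and adjusted over the list alone 10 rose. The defence list had adjusted p = 1.8e-12, and adjusted p = 0.075 with an estimated correlation (0.037, 0.038 and 0.047 without Pectin 2, Inulin 1 and Inulin 2). Duoxa2, the maturation factor of Duox2, had a log2 fold change of 3.63 ± 0.70. Among 26 interferon-stimulated genes 2 rose over all genes and 9 adjusted over the list alone (median 0.74, or 1.30 without Control 4, adjusted p = 3e-08, and adjusted p = 0.22 with an estimated correlation). None of the 22 proliferation genes or 27 oxidative phosphorylation genes passed over all genes. Each nevertheless had a positive fold change, and 17 and 15 were higher adjusted over the list alone (medians 1.17 and 0.38). Their list tests gave adjusted p = 7.8e-13 and 9.9e-13, and adjusted p = 0.22 and 0.17 with an estimated correlation. Of 17 stress response genes 3 rose over all genes, and 9 rose and 1 fell adjusted over the list alone (median 0.66, adjusted p = 1.1e-05, and adjusted p = 0.16 with an estimated correlation).

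Lists of several cell types were called beside these groups. Paneth cell (median 1.07), enteroendocrine (0.85), myeloid (0.81), T cell (0.66) and goblet cell (0.60) lists were called up, with 0, 1, 1, 1 and 2 members higher over all genes and 5, 5, 1, 7 and 5 adjusted over the list alone. With an estimated correlation they had adjusted p = 0.23, 0.091, 0.24, 0.44 and 0.22. The B cell list was called up with its mean of 0.33 (adjusted p = 0.00031, and adjusted p = 0.5 with an estimated correlation). Its median was −0.46, since 9 of 16 members were negative, while Igha and Igkc rose. Inflammation (0.39), class II (0.92) and ketone body (0.37) lists were called up and tuft cell (−0.47) and nerve (−0.61) lists down. None of these held (adjusted p = 0.25, 0.6, 0.22, 0.5 and 0.56 with an estimated correlation). Camera lost the ketone body call without Control 1, Control 4 or Pectin 4 (adjusted p up to 0.095), the class II call without Control 2, Control 4 or Pectin 3 (up to 0.17) and the B cell call without Control 2 (0.094). It lost the tuft cell call without Control 1 (median −0.26) or Pectin 4 (−0.28; up to 0.13) and the nerve call without Control 2, 3 or 4 or Pectin 1, 2 or 3 (up to 0.13). The nerve median was −0.40 without Pectin 3 and −1.12 without Pectin 4, that of class II genes 1.83 without Control 3 and that of the inflammation list 0.20 without Pectin 3. T cell markers had medians of 0.33, 1.90, 0.43 and 1.01 without Control 2, Control 3, Control 4 and Pectin 4. For B cell markers the median was −0.86, 0.94, −0.80 and −0.06 without Control 2, Control 3, Pectin 2 and Pectin 4.

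Individual libraries mattered for pectin. The count was 51 without Pectin 3, 83 without Pectin 2, 92 without Pectin 1 and 183 without Pectin 4. It was 112, 137, 199 and 530 without Control 1, 2, 3 and 4. Igha, Zbp1, Bmp1, Abcc6, Abcc5, Gsr, Asns and Cck kept their calls in each of these omissions. In the 11 other settings only Zbp1 and Bmp1 of these always passed. Gsr lost its call in 3 of them (adjusted p up to 0.119), Abcc6 in 2 (up to 0.078) and Igha, Abcc5, Asns and Cck in 1 each (up to 0.0801). Duox2 lost its call without Control 1 or Pectin 3 (adjusted p = 0.0622 and 0.0732), Duoxa2 without Pectin 3 (0.0551) and Igkc without Control 1, Control 2 or Pectin 1 (up to 0.0592). Reg3a passed only without Control 4 or Pectin 2 (otherwise up to 0.0741), and Lypd8 only without Control 4 (otherwise up to 0.123). The DESeq2 Wald test called 857 genes, a model of these groups alone 48, and library totals alone 126 (51 higher, 75 lower).

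**Figure D2:**
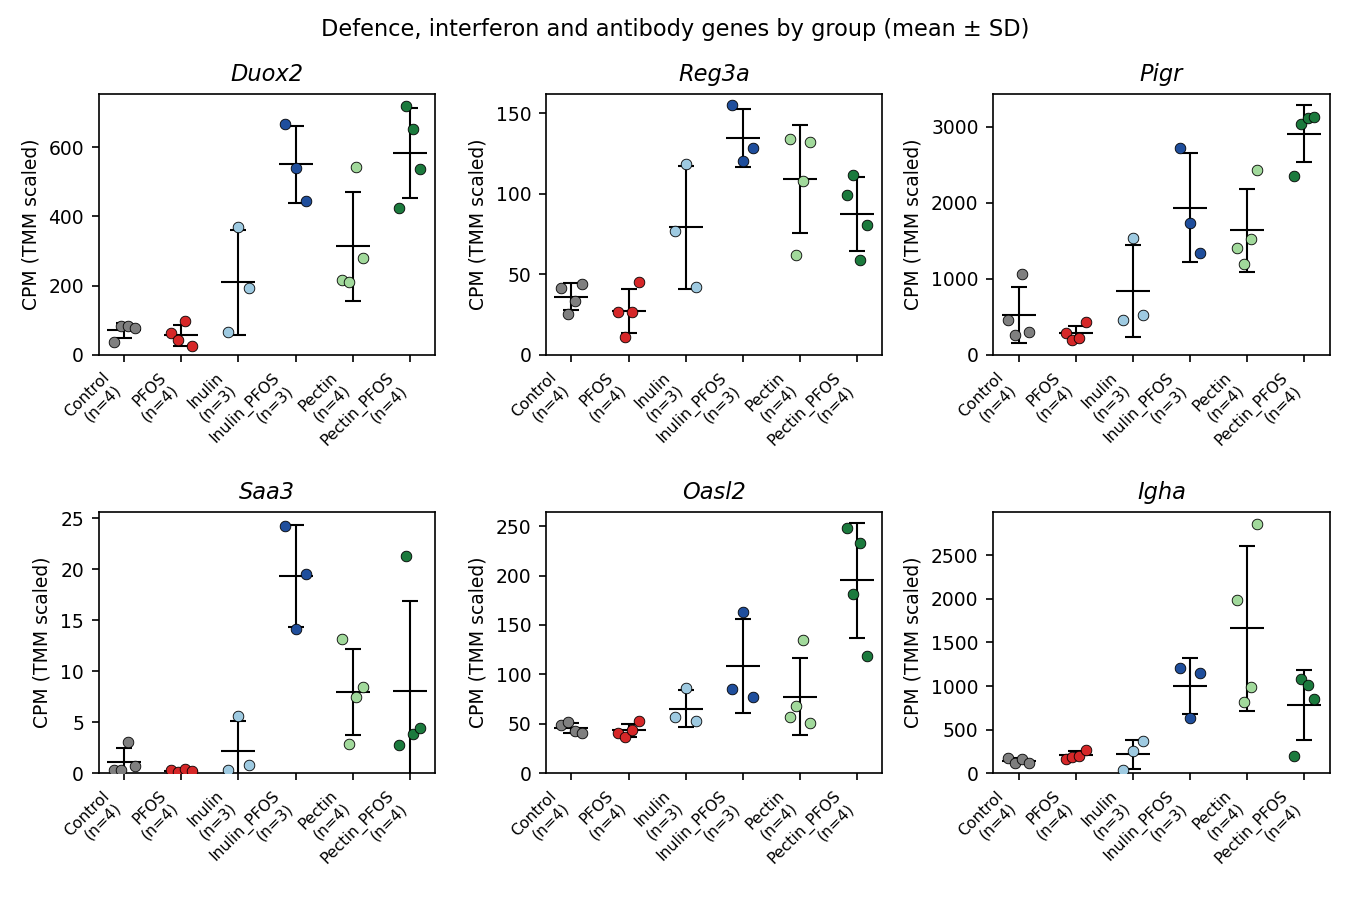
Expression in CPM of defence, interferon and antibody genes on the vertical axis (from 0) in the 6 groups on the horizontal axis, with points for the 22 libraries and bars for the group mean ± SD. Duox2 averaged 70.7 CPM in Control, 57.3 in PFOS, 313 in Pectin, 550 in Inulin_PFOS and 583 in Pectin_PFOS.

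Inulin_PFOS vs Inulin (n = 3 each) addressed PFOS on the inulin diet, and edgeR called 11 genes higher and 14 lower. Mthfd2, a mitochondrial folate enzyme (chromosome 6, 83305691 to 83325908), rose from 3.55 ± 1.18 to 20.2 ± 4.25 CPM (SD; log2 fold change 2.51 ± 0.32, adjusted p = 0.00108). Jdp2, a bZIP transcription repressor (chromosome 12, 85599105 to 85639878), rose from 3.95 ± 0.818 to 18.4 ± 5.4 CPM (2.21 ± 0.28, adjusted p = 0.00108). Asns (chromosome 6, 7675169 to 7693254) rose from 11.5 ± 2.01 to 47 ± 15.9 CPM (2.03 ± 0.30, adjusted p = 0.00523). The stress-responsive factor gene Atf5 (1.48 ± 0.27, adjusted p = 0.0203) and the methionyl-tRNA synthetase gene Mars (1.30 ± 0.22, adjusted p = 0.0136) rose too. Bmp1 fell from 138 ± 60.9 to 27.2 ± 11.2 CPM (−2.34 ± 0.38, adjusted p = 0.0136). Acot1, an acyl-CoA thioesterase gene with close copies and therefore uncertain (chromosome 12, 84009502 to 84017670), fell by 1.86 on the log2 scale (SE 0.36, adjusted p = 0.0368).

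Among these 25 genes, no defence, oxidative phosphorylation or interferon-stimulated gene passed, although 23 of 24, 27 of 27 and 21 of 26 had positive fold changes (medians 1.40, 0.43 and 1.18). Adjusted over the list alone, 3, 0 and 11 were higher. The lists had adjusted p = 4.2e-08, 4.2e-08 and 1.3e-07, and adjusted p = 0.32, 0.33 and 0.33 with an estimated correlation. PPAR-alpha target genes were negative in 28 of 31 members (median −0.47), with Acot1 lower over all genes and 9 adjusted over the list alone. That list had adjusted p = 1.2e-07, and adjusted p = 0.33 with an estimated correlation. Its members Pdk4 (−1.33 ± 0.53) and Cpt1a (−0.95 ± 0.33) did not pass over all genes (adjusted p = 0.191 and 0.156). Clock genes were negative in 15 of 17 (median −1.06), and 5 were lower adjusted over the list alone (adjusted p = 0.00021, and adjusted p = 0.33 with an estimated correlation). Drug metabolism genes under PXR and CAR were negative in 21 of 25 (median −0.39), with 4 lower adjusted over the list alone (adjusted p = 0.00084, and adjusted p = 0.51 with an estimated correlation). The median was 0.86 for defence genes without Inulin_PFOS 1, −0.31 for PPAR-alpha genes without Inulin 1 and −0.60 for drug metabolism genes without Inulin 2.

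Fibroblast, muscle and nerve markers leaned up here, while in Inulin vs Control, which shares the Inulin libraries, they leaned down. All 12 muscle markers (median 1.36) and all 12 fibroblast markers (0.91) were positive, with 10 and 0 higher adjusted over the list alone. The lists had adjusted p = 1.2e-07 and 6.7e-06, and adjusted p = 0.37 for both with an estimated correlation. Myeloid (1.13), Paneth cell (1.18), goblet cell (0.75), nerve (0.79), T cell (0.70), proliferation (0.50) and inflammation (0.37) lists were also called up, with adjusted p between 0.33 and 0.80 with an estimated correlation. Camera lost the proliferation call without Inulin 1 (median 0.08), Inulin 2 (0.26) or Inulin_PFOS 1 (0.05; adjusted p up to 0.54), and the T cell call without Inulin 1 (0.33) or Inulin_PFOS 2 (0.46; up to 0.33). The inflammation call was lost without Inulin 1 (0.11) or Inulin_PFOS 2 (up to 0.33), and the nerve call without Inulin 3 or Inulin_PFOS 2 (0.26; up to 0.49). Other medians were 1.27 and 1.00 for proliferation and inflammation without Inulin 3, 1.20 for nerve without Inulin 2, 0.77 for muscle without Inulin_PFOS 2 and 0.44 for goblet cells without Inulin_PFOS 3. The number of genes called was 2 without Inulin 1 or Inulin_PFOS 1, 3 without Inulin_PFOS 3, 10 without Inulin_PFOS 2, 53 without Inulin 2, 147 without Inulin 3 and 50 without Pectin_PFOS 1. The DESeq2 Wald test called 497, and a model of these groups alone 0. Mthfd2 and Jdp2 kept their calls in each omission of a library, but each lost its call in 1 of 11 other settings (adjusted p = 0.0632 and 0.064). Asns lost its call without Inulin 1 (adjusted p = 0.0851) or Inulin_PFOS 1 (0.0667), and Bmp1, Atf5 and Mars without Inulin 1, Inulin_PFOS 1 or Inulin_PFOS 3 (up to 0.122, 0.258 and 0.197). Acot1 lost its call without any 1 Inulin_PFOS library, Inulin 1 or Inulin 2 (up to 0.221).

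**Figure D3:**
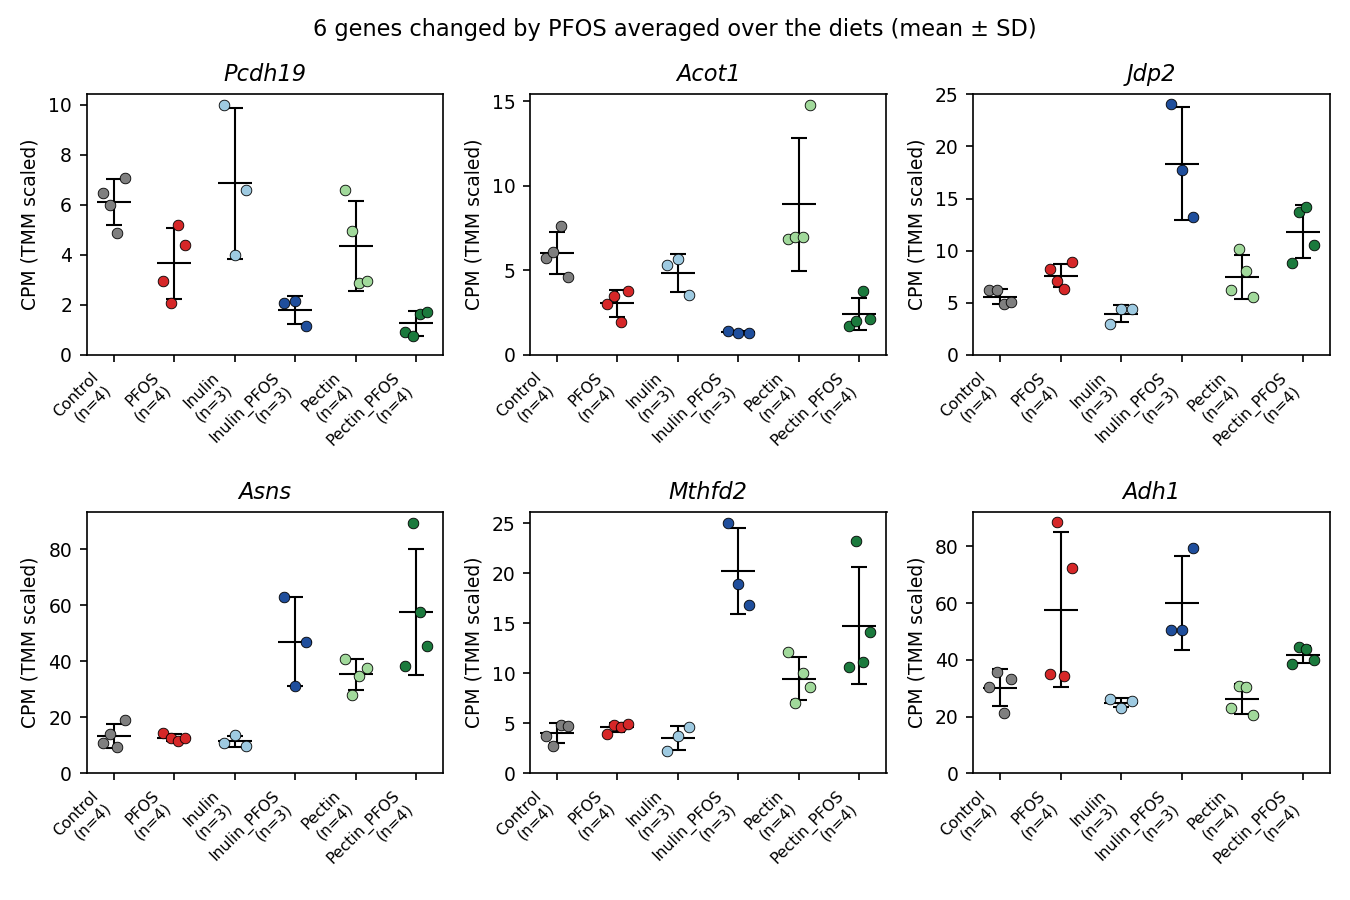
Expression in CPM of 6 genes called in the PFOS effect averaged over diets, on the vertical axis (from 0), in the 6 groups on the horizontal axis, with points for libraries and bars for the group mean ± SD. Acot1 averaged 6.02, 4.85 and 8.9 CPM in the unexposed groups on cellulose, inulin and pectin, and 3.05, 1.33 and 2.4 CPM in the exposed ones.

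Pectin_PFOS vs Pectin (n = 4 each) addressed PFOS on the pectin diet, and 12 of 17 markers of absorptive enterocytes rose. Their list test gave adjusted p = 1.8e-10, and adjusted p = 0.19 with an estimated correlation. Anpep, the brush border aminopeptidase N (chromosome 7, 79821803 to 79848210), rose from 5500 ± 1630 to 22300 ± 10800 CPM (SD; log2 fold change 2.02 ± 0.36, adjusted p = 0.00286). Slc5a1, the sodium-glucose cotransporter (chromosome 5, 33104219 to 33162870), rose from 884 ± 150 to 2870 ± 860 CPM (1.70 ± 0.29, adjusted p = 0.00249). The peptidase genes Ace (1.84 ± 0.31) and Mep1b (1.32 ± 0.25), the amino acid transporter gene Slc43a2 (2.04 ± 0.33) and Cubn, a receptor for intrinsic factor and cobalamin (1.86 ± 0.29), rose with adjusted p from 0.00216 to 0.00385. The collagen gene Col3a1 fell from 123 ± 10.2 to 40.3 ± 16.5 CPM (−1.61 ± 0.38, adjusted p = 0.0089), and the matrix protein gene Dpt fell as well (−1.44 ± 0.30, adjusted p = 0.00563). Acot1 fell by 1.88 on the log2 scale (SE 0.31, adjusted p = 0.00216).

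Of 3277 genes called, 1790 were higher and 1487 lower. Among the 17 enterocyte markers 0 fell and 5 did not pass, and 13 were higher adjusted over the list alone (median 1.38). Of 20 lipid absorption genes 8 rose and 1 fell, with the same counts adjusted over the list alone (median 0.55, adjusted p = 0.0013, and adjusted p = 0.78 with an estimated correlation). Those that rose included the sterol exporter genes Abcg8 (1.74 ± 0.27) and Abcg5 (1.43 ± 0.27), which overlap so that their separate values are uncertain. Npc1l1, which imports cholesterol (1.27 ± 0.27), and Mogat2, which resynthesises triglyceride (0.91 ± 0.22), rose as well. Cholesterol synthesis genes rose in 3 of 25, and in 7 adjusted over the list alone (median 0.50, adjusted p = 0.0025, and adjusted p = 0.78 with an estimated correlation). Tight junction genes rose in 4 of 18, interferon-stimulated genes in 4 of 26, stress response genes in 3 of 17 and clock genes in 2 of 17. Adjusted over the list alone 4, 4, 6 and 2 were higher, with adjusted p = 0.78 for each list with an estimated correlation. Examples were F11r, a junctional adhesion molecule (1.14 ± 0.24), Oasl2 (1.33 ± 0.30), Trib3 (1.14 ± 0.33) and Tef (1.29 ± 0.34). Pectin 4 had a lipid absorption score of −1.31, against 0.03 to 0.52 in the other Pectin libraries. Without it camera lost the lipid absorption (median 0.39, adjusted p = 0.06), interferon (0.36, 0.21) and clock calls (0.36, 0.1), while without Pectin 3 the first 2 had medians of 0.89 and 0.80. The clock call was also lost without Control 4, PFOS 4, Pectin 3 or Pectin_PFOS 3 or 4 (up to 0.069), and the tight junction call without Pectin_PFOS 1 (0.33, 0.056). Cholesterol synthesis genes had a median of 0.33 without Pectin_PFOS 1.

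Lower groups were led by 7 of 12 fibroblast markers (median −1.06, adjusted p = 8.6e-06) and 6 of 11 Paneth cell markers (median −1.39, adjusted p = 0.002), with 8 each adjusted over the list alone. Both list calls were lost (adjusted p = 0.78 with an estimated correlation). Muscle (median −0.98), B cell (−1.70), myeloid (−0.92), proliferation (−0.64) and mitochondrially encoded genes (−0.72) were also called down, each with adjusted p = 0.78 with an estimated correlation. In these lists 0, 1, 1, 2 and 3 members fell over all genes and 0, 0, 0, 2 and 3 adjusted over the list alone. Pectin_PFOS 1 had a myeloid score of −1.38 and a proliferation score of −0.59, against −0.05 to 0.53 and 0.44 to 0.51 in the other Pectin_PFOS libraries. Without it the proliferation call was lost (median −0.41, adjusted p = 0.056 in camera), and the myeloid median was −0.61 (0.048). Itln1, an intelectin that binds microbial glycans and has close copies, so that its value is uncertain, fell by 1.85 on the log2 scale (SE 0.44, adjusted p = 0.00982). The complex I subunit gene mt-Nd3 fell by 2.46 (SE 0.40, adjusted p = 0.00216). Mitochondrial genes took 2.85% to 3.51% of the counts of Pectin_PFOS libraries and 3.88% to 7.36% of those of Pectin. Fewer genes were called without Pectin_PFOS 1 (1360), Pectin 1 (1567) or Pectin 2 (1686) and by limma on TPM (1410), and library totals alone gave 576 higher and 2386 lower. Trib3 lost its call without Pectin 4 or Pectin_PFOS 1 (adjusted p = 0.0568 and 0.0665), while the other genes named above passed in each omission of a library. Of the latter, Col3a1, Mogat2, F11r and Tef each lost their call in 1 of 11 other settings (up to 0.0738). Pdk4, which restrains pyruvate oxidation, fell by 1.43 on the log2 scale (SE 0.46, adjusted p = 0.0347), but not without Pectin 1, Pectin 2 or Pectin_PFOS 2, 3 or 4 (up to 0.0906).

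Inulin_PFOS vs PFOS compared inulin with cellulose among exposed mice, and 12 of 24 epithelial defence genes rose. Duox2 went from 57.3 ± 30.3 CPM in PFOS (n = 4) to 550 ± 111 CPM in Inulin_PFOS (n = 3; log2 fold change 3.26 ± 0.49, adjusted p = 0.00257). Pigr, the receptor that carries immunoglobulin A across the epithelium (chromosome 1, 130826684 to 130852249), rose from 284 ± 102 to 1930 ± 713 CPM (2.77 ± 0.47, adjusted p = 0.00482). The antimicrobial lectin gene Reg3a (2.30 ± 0.38), the acute phase gene Saa3 (6.07 ± 1.01), Zbp1 (3.34 ± 0.56) and the fucosyltransferase gene Fut2 (4.49 ± 0.81) rose with adjusted p from 0.0043 to 0.00715. Asns (1.88 ± 0.27), Gsr (1.41 ± 0.24) and Bdh1, an enzyme gene of ketone body use (1.08 ± 0.18), were also higher, with adjusted p from 0.00212 to 0.00482.

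Of 416 genes called, 290 were higher and 126 lower, with 8 immunoglobulin variable segments among the higher ones. Defence genes rose in 12 of 24 members, 0 fell, and 14 were higher adjusted over the list alone (median 1.79). This call held, with adjusted p = 3.5e-15, and adjusted p = 0.027 with an estimated correlation, but not without PFOS 4 or Control 3 (0.077 and 0.051). Interferon-stimulated genes rose in 5 of 26 over all genes and in 16 adjusted over the list alone (median 1.36), and oxidative phosphorylation genes in 2 and 21 of 27 (median 0.52). Their adjusted p of 5.5e-13 and 1.2e-11 became adjusted p = 0.15 for both with an estimated correlation (0.049 for the former without Inulin_PFOS 3). Cholesterol synthesis (0.60), inflammation (1.21), goblet cell (0.72), myeloid (0.94), stress response (0.39), T cell (0.69) and muscle (0.98) lists were called up. These had adjusted p = 0.47, 0.15, 0.21, 0.29, 0.15, 0.62 and 0.62 with an estimated correlation. In the same order 0, 1, 3, 0, 2, 0 and 0 members were higher over all genes, and 12, 6, 5, 5, 5, 0 and 0 adjusted over the list alone. Class II, ketone body, B cell, tuft cell, short-chain fatty acid, enteroendocrine, NRF2 target and Paneth cell lists were called up with medians from 0.15 to 0.91 (adjusted p from 0.15 to 0.66 with an estimated correlation). The medians of the NRF2, enteroendocrine and B cell lists turned negative under library totals alone.

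Some of these calls for Inulin_PFOS vs PFOS rested on single libraries in camera. The muscle call was lost without Inulin_PFOS 2 (median 0.30, adjusted p = 0.25), the short-chain fatty acid call without Inulin_PFOS 1 (0.36, 0.088) and the NRF2 call without PFOS 3 or Inulin_PFOS 3 (up to 0.082). Paneth cell markers lost theirs without PFOS 1, PFOS 4 or Inulin_PFOS 1 (0.26 without the last; up to 0.38). Tuft cell markers did so without PFOS 2 (0.30) or Inulin_PFOS 1 (0.26; up to 0.21), and enteroendocrine markers without PFOS 1 or Inulin_PFOS 3 (0.18 without the latter; up to 0.094). The B cell call was lost without PFOS 1 (−0.23, 0.21), and its median of 0.15 was −0.02, 0.05 and 0.88 without PFOS 2, 3 and 4 and 0.01, 0.02 and 0.37 without Inulin_PFOS 1, 2 and 3. Class II genes had medians of 0.60, 0.60, 0.59 and 2.29 without PFOS 1, 2, 3 and 4, and T cell markers 1.58 without PFOS 4. The stress response median was 0.25 without PFOS 3 and 0.20 without Inulin_PFOS 1, and that of goblet cells 0.31 without Inulin_PFOS 3.

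Clock genes included 1 higher and 2 lower members of 17 over all genes, and 1 and 7 adjusted over the list alone (median −0.91). Clock genes had adjusted p = 0.00044, and adjusted p = 0.19 with an estimated correlation. Drug metabolism genes were negative in 21 of 25, with 1 lower over all genes, and 1 higher and 8 lower adjusted over the list alone (median −0.61, adjusted p = 0.0027, and adjusted p = 0.48 with an estimated correlation). That call was lost without PFOS 4 (adjusted p = 0.051 in camera), and its median was −0.39 without PFOS 2 or Inulin_PFOS 2, while that of the clock genes was −0.60 without PFOS 2. Omission of 1 library left 145, 73 and 131 genes (PFOS 1, 2 and 3) or 78, 213 and 123 (Inulin_PFOS 1, 2 and 3). The DESeq2 Wald test called 1110, and a model of these groups alone 1629. Directions moved with the scaling, with 141 higher and 858 lower genes by library totals alone. Limma on TPM, which differs in its values and test as well, gave 140 higher and 2483 lower. Duox2, Pigr, Reg3a, Saa3, Zbp1, Fut2, Asns, Gsr and Bdh1 kept their calls in each omission of a library. Of 10 named genes that did so here, only 8 also passed in each other setting, among them Duox2, Pigr, Reg3a, Saa3, Zbp1 and Fut2.

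Pectin_PFOS vs PFOS (n = 4 each) compared pectin with cellulose among exposed mice. Pigr rose from 284 ± 102 to 2910 ± 371 CPM (SD; log2 fold change 3.35 ± 0.46, adjusted p = 0.000631), and Duox2 from 57.3 ± 30.3 to 583 ± 130 CPM (3.35 ± 0.48, adjusted p = 0.00064). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), rose from 57.6 ± 12.3 to 1010 ± 562 CPM (4.13 ± 0.58, adjusted p = 0.00064). The interferon-stimulated genes Oasl2 (2.17 ± 0.31), Oas1a (1.84 ± 0.27) and Usp18 (2.71 ± 0.48) rose with adjusted p from 0.000632 to 0.00206. Asns rose from 12.8 ± 1.15 to 57.6 ± 22.6 CPM (2.17 ± 0.26, adjusted p = 0.00017), and so did the ER chaperone gene Hspa5 (1.12 ± 0.23) and Manf, a factor induced by ER stress (1.17 ± 0.23). Pdgfra, a receptor of intestinal fibroblasts (−1.85 ± 0.35, adjusted p = 0.00326), and Pdk4 (−2.06 ± 0.47, adjusted p = 0.00791) fell.

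The 2526 called genes comprised 1213 higher and 1313 lower, with 19 immunoglobulin variable segments among the higher ones. Interferon-stimulated genes rose in 17 of 26 members, none fell, and 20 were higher adjusted over the list alone (median 1.76, adjusted p = 6.6e-15, and adjusted p = 0.097 with an estimated correlation). Stress response genes rose in 10 of 17, and in 14 adjusted over the list alone (median 1.00). This call held, with adjusted p = 1.6e-09, and adjusted p = 0.048 with an estimated correlation, but not without any 1 PFOS library or Pectin_PFOS 3 or 4 (up to 0.12), nor without Control 1 or 2, Inulin_PFOS 2 or 3 or Pectin 3 or 4 (up to 0.11). Defence genes rose in 11 of 24, enterocyte markers in 9 of 17 and goblet cell markers in 5 of 12, and in 12, 9 and 7 adjusted over the list alone, where 1 goblet cell marker was lower (medians 1.44, 0.88 and 0.79). These lists had adjusted p = 1.9e-09, 3.5e-08 and 0.00096, and adjusted p = 0.096, 0.13 and 0.42 with an estimated correlation (0.037 and 0.045 for the first without Inulin 1 and 2). Examples were Lypd8, which keeps flagellated bacteria from the epithelium (2.54 ± 0.39), Mep1b (1.71 ± 0.26) and the mucus protein gene Fcgbp (1.35 ± 0.23). Oxidative phosphorylation genes rose in 11 of 27 and in 13 adjusted over the list alone (median 0.37, adjusted p = 1.6e-05, and adjusted p = 0.42 with an estimated correlation). That median turned negative under library totals alone, as did those of the tight junction (0.39), short-chain fatty acid (0.31) and PPAR-alpha (0.20) lists. The latter had adjusted p = 0.51, 0.42 and 0.59 with an estimated correlation. Camera lost the tight junction call without PFOS 3, PFOS 4 (median 0.25), Pectin 4 or Pectin_PFOS 1 or 2 (adjusted p up to 0.19), and the short-chain fatty acid call without PFOS 2 (0.072), with a median of 0.48 without Pectin_PFOS 3. It lost the PPAR-alpha call without PFOS 1, PFOS 3, Pectin_PFOS 1 (median 0.04) or Pectin_PFOS 3 (up to 0.43), with 0.40 without PFOS 4.

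Lists of other cells were called as well. T cell markers were higher in 3 of 16 (median 1.34) and fibroblast markers lower in 9 of 12 (−1.29), and 3 and 12 adjusted over the list alone. Muscle (−0.74), nerve (−0.87) and red blood cell (−2.27) lists were called down, the last with 3 of 4 genes lower. In the order T cell, fibroblast, muscle, nerve and red blood cell the lists had adjusted p = 0.51, 0.37, 0.59, 0.51 and 0.51 with an estimated correlation. PFOS 2 had a red blood cell score of 2.60, against −0.68 to 0.35 in the other PFOS libraries, and without it Hbb-bs, whose value is uncertain, went from −2.65 to −1.42 and lost its call (adjusted p = 0.163). Camera lost the red blood cell call without PFOS 2 (median −1.08), Pectin 4 or Pectin_PFOS 3 or 4 (up to 0.17), the muscle call without Pectin_PFOS 1 (0.073) and the nerve call without PFOS 1 or Pectin_PFOS 1 (up to 0.068). Mitochondrially encoded genes fell in 4 of 13, and in 9 adjusted over the list alone (median −1.03, adjusted p = 0.00011, and adjusted p = 0.51 with an estimated correlation). Cholesterol synthesis (0.56), class II (1.92), enteroendocrine (0.57), proliferation (0.61), lipid absorption (0.47) and Paneth cell (0.41) lists were called up, with adjusted p between 0.37 and 0.59 with an estimated correlation. The Paneth cell call was lost without PFOS 1 (median 0.27) or Pectin_PFOS 3 (0.10; adjusted p up to 0.19 in camera), with 0.93 without PFOS 3. Without PFOS 4 the class II, T cell and enteroendocrine medians were 3.19, 2.16 and 0.98, and without Pectin_PFOS 1 that of cholesterol synthesis was 0.35. Library totals alone gave 299 higher and 3530 lower genes. Fewer were called without PFOS 3 (1265), Pectin_PFOS 1 (1283), PFOS 2 (1538) or Pectin_PFOS 2 (1631). Pigr, Duox2, Nos2, Oasl2, Oas1a, Usp18, Asns, Hspa5, Manf, Pdgfra, Pdk4, Lypd8, Mep1b and Fcgbp passed in each omission of a library. Of 45 named genes that did so in this comparison, only 34 also passed in each of the other settings.

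**Figure D4:**
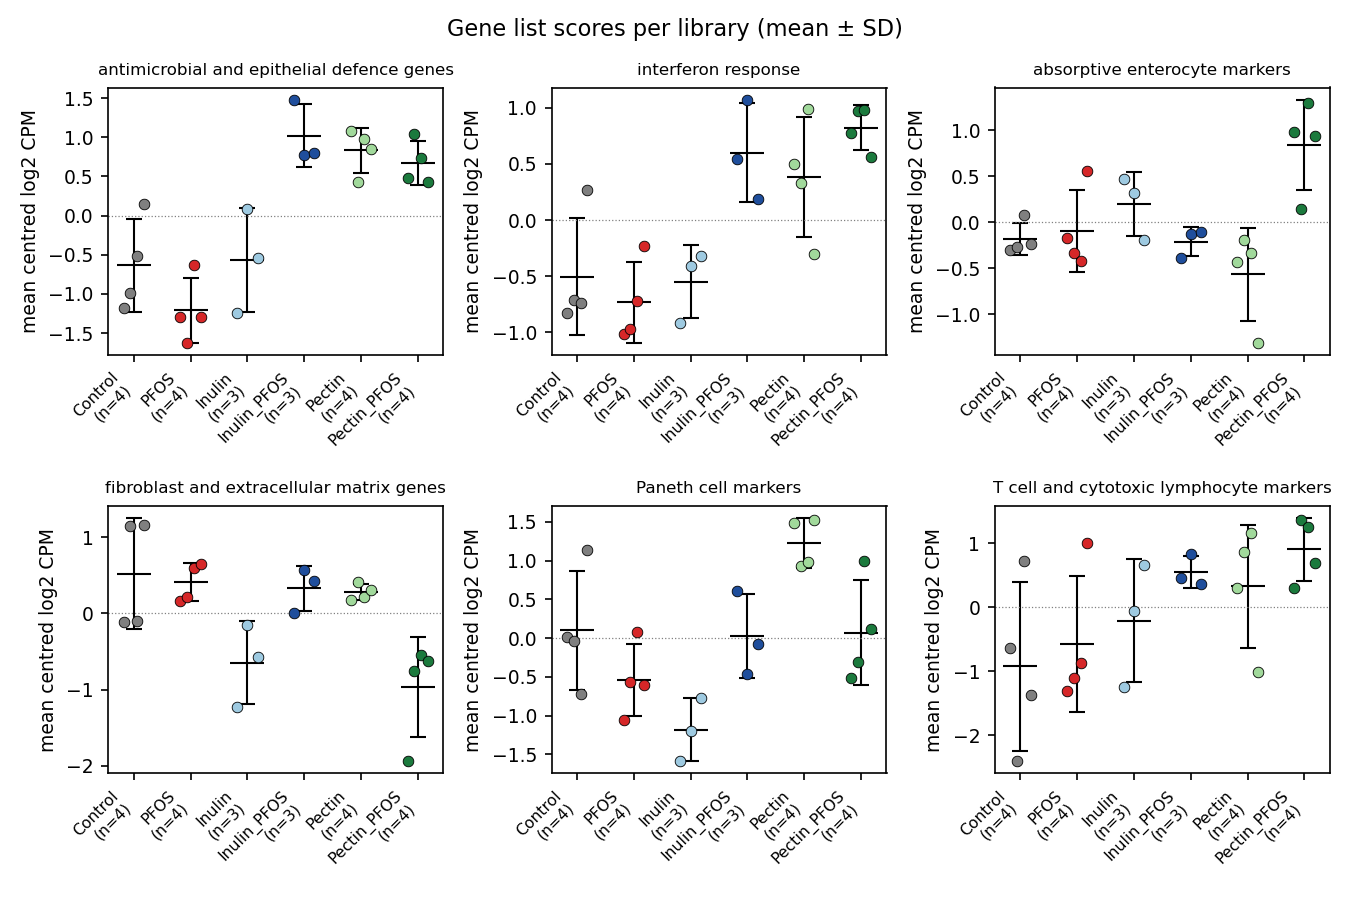
Scores of gene lists (mean log2 CPM of the members, centred over all libraries) on the vertical axis in the 6 groups on the horizontal axis, with points for libraries and bars for the group mean ± SD. The defence score averaged −0.63 in Control, −1.21 in PFOS and −0.56 in Inulin, against 1.02 in Inulin_PFOS, 0.84 in Pectin and 0.67 in Pectin_PFOS.

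Interaction terms tested whether the PFOS effect differed between fibres, and no gene passed. With inulin, the smallest adjusted p was 0.0984, shared by Mthfd2 (difference of log2 fold changes 2.31 ± 0.41), Asns (2.10 ± 0.39), Jdp2 (1.76 ± 0.35), the iron-binding defence gene Ltf (3.86 ± 0.72) and Khdrbs3 (1.55 ± 0.32). With pectin it was 0.159 for Nfkb2, a subunit of NF-kappaB (1.35 ± 0.23). edgeR called 0 genes in either interaction, with 3099 and 1953 at an unadjusted p under 0.05, and the DESeq2 Wald test called 659 and 135. The inulin interaction called 767 genes without Control 1 and 17 without Inulin 3, and the pectin interaction 4 without Control 4 and 2 without Pectin_PFOS 2. Defence genes were positive in 22 of 24 members of the inulin interaction, with 14 higher adjusted over the list alone (median 1.88, adjusted p = 1.4e-08, and adjusted p = 0.22 with an estimated correlation). Enterocyte markers were positive in 16 of 17 in the pectin interaction, with 13 higher adjusted over the list alone (median 1.34, adjusted p = 5.2e-14, and adjusted p = 0.061 with an estimated correlation). The latter was 0.025, 0.049, 0.02, 0.039 and 0.035 without PFOS 4, Inulin 1, Inulin 3, Pectin_PFOS 1 and Pectin_PFOS 2.

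Averaged over the 3 diets, PFOS lowered 8 genes and raised 17. Acot1 fell by 1.57 on the log2 scale (SE 0.19, adjusted p = 0.000645). Jdp2 (1.11 ± 0.14, adjusted p = 0.000963), Mthfd2 (1.11 ± 0.16, adjusted p = 0.004) and Adh1, an alcohol and retinol dehydrogenase gene (0.96 ± 0.16, adjusted p = 0.0104), rose. On cellulose, inulin and pectin in turn, the PFOS effect was 0.45, 2.21 and 0.66 for Jdp2, 0.20, 2.51 and 0.64 for Mthfd2 and −0.06, 2.03 and 0.70 for Asns. Of these 9 values only those on inulin and that of Jdp2 on pectin passed (adjusted p = 0.0458 for the latter). The cell adhesion gene Pcdh19 fell (−1.48 ± 0.22, adjusted p = 0.00487). Asns rose by 0.89 ± 0.16 (adjusted p = 0.0161), but not without Inulin 1, Inulin 3 or Inulin_PFOS 1 (0.0609, 0.0633 and 0.0708). Cpt1a (−0.33 ± 0.17), Pdk4 (−0.78 ± 0.27) and Angptl4 (−0.15 ± 0.26) did not pass (adjusted p = 0.38, 0.22 and 0.816).

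PPAR-alpha target genes were negative in 25 of 31 members of the average, with Acot1 lower over all genes and 2 adjusted over the list alone (median −0.17, adjusted p = 0.00016, and adjusted p = 0.79 with an estimated correlation). Interferon-stimulated genes were positive in 25 of 26, with 0 over all genes and 6 higher adjusted over the list alone (median 0.40, adjusted p = 7.9e-07, and adjusted p = 0.68 with an estimated correlation). B cell markers were called down (median −1.75) and enterocyte markers up (0.29), with 10 lower and 4 higher adjusted over the list alone. These had adjusted p = 0.79 and 0.68 with an estimated correlation. T cell, stress response, goblet cell, lipid absorption, cholesterol synthesis, oxidative phosphorylation and tight junction lists were called up (medians from 0.10 to 0.44) and mitochondrially encoded genes down (−0.39). Their adjusted p lay between 0.68 and 0.94 with an estimated correlation. Of 22 omissions of a library, 12 ended the tight junction call, 11 the oxidative phosphorylation call and 10 the cholesterol synthesis call (adjusted p up to 0.2, 0.38 and 0.54 in camera, with medians down to 0.08, 0.06 and 0.04). The lipid absorption call was lost without PFOS 4 or Pectin 4 (up to 0.3), and the goblet cell call without Inulin_PFOS 3 or Pectin 4 (up to 0.14), with medians from 0.08 to 0.24 over the omissions. Without Control 4 the interferon median was 0.63 and that of mitochondrially encoded genes −0.20. B cell markers had a median of −1.14 without Inulin 3, and T cell markers 0.85, 0.19 and 0.72 without Control 3, PFOS 4 and Inulin 3. The number of genes was 8 without Inulin_PFOS 1, 9 without Inulin 1, 11 without Inulin 3, 12 without Pectin 1 or Pectin 2 and 13 without PFOS 3. It was 14 without PFOS 1, Inulin_PFOS 2 or Pectin_PFOS 3, 15 without Inulin_PFOS 3, 16 without Control 4, 40 without Pectin 4, 41 without Pectin 3 and 42 without Inulin 2. The DESeq2 Wald test called 214, and library totals alone 7 higher and 8 lower. Acot1, Jdp2, Mthfd2, Adh1 and Pcdh19 passed in each omission, but only 3 of these 5 genes also passed in each of the other settings.

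Fibre responses with and without PFOS overlapped. Of 162 genes higher in Pectin vs Control, 125 were also higher in Pectin_PFOS vs PFOS, which shares no libraries, against 12.5 for independent lists (Fisher's exact test, one-sided, p = 4.4e-107). In Inulin_PFOS vs PFOS 82 of them were higher, against 2.98 (Fisher's exact test, p = 2.4e-101). Of 151 lower genes, 40 and 25 were also lower, against 12.6 and 1.21 (Fisher's exact test, p = 2.5e-11 and 3.2e-26). Genes are not independent, so these p-values describe the overlap only. Inulin_PFOS vs PFOS and Pectin_PFOS vs PFOS share the PFOS libraries, and had in common 231 of 290 higher and 76 of 126 lower genes of the former, against 22.3 and 10.5 for independent lists. Simulated unchanged groups shared at most 1, but unchanged genes are seldom called, so this count is no baseline for the overlap. Fold changes of these comparisons correlated across genes at 0.647, against 0.455 for simulated unchanged groups, with a covariance of 0.379 against 0.0867. With the PFOS libraries divided between the comparisons, the correlation was 0.37 to 0.517 and the covariance 0.267 to 0.334, and 3 to 49 higher and 0 to 7 lower genes were shared.

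PFOS responses on the fermentable fibres shared about as many genes as independent lists would. Of Inulin_PFOS vs Inulin, 1 of 11 higher and 1 of 14 lower genes were called in the same direction in Pectin_PFOS vs Pectin, against 1.25 and 1.32 for independent lists (Fisher's exact test, one-sided, p = 0.73 and 0.75). The 200 genes with the smallest p in PFOS vs Control, none of which passed, had the same sign in 86.5% of cases in Pectin_PFOS vs Pectin and in 21.5% in Inulin_PFOS vs Inulin. Exact permutation of the library labels, two-sided, gave p = 0.229 over 70 labelings and p = 0.1 over 20, the latter being the smallest that design allows.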

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

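The tests of the 3 patterns weighed here, and the counts of other sample splits for the pairs of groups, were chosen after the results had been seen, whereas the splits for the interactions and for the averaged effect were planned.

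The 3277 genes called between Pectin_PFOS and Pectin included 12 of 17 enterocyte markers, all higher, and 7 of 12 fibroblast and 6 of 11 Paneth cell markers, all lower. A GC trend between libraries is argued against as the whole cause by 3026 genes called once it was removed (1893 higher, 1133 lower). Of these, 2422 had been called in the same direction before. A single library is argued against as the whole cause by 1360 genes called without Pectin_PFOS replicate 1. A smaller share of all non-epithelial tissue was taken to lower T cell and fibroblast markers alike. The T cell list was not called, and these scores moved apart by 1.82 (two-sided exact permutation p = 0.029, 70 labelings). Without Pectin 4 they moved apart by 1.36 (p = 0.029, exact permutation, 35 labelings). T cells also lie within the epithelium, so these scores do not decide the matter and this cause stays open. B cell, myeloid and muscle lists were called down with the fibroblast list (adjusted p = 0.78 with an estimated correlation). The enterocyte score gained 2.56 on the Paneth cell score (exact permutation p = 0.029). This argues against a smaller share of fibroblast, muscle and nerve tissue only if no Paneth cells were lost with it, which was not tested. A change in the enterocytes or in their share may underlie the pattern as a hypothesis. PFOS on this diet, position along the gut and sampling depth stay open as causes (gut segment lists were not called).

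Acot1, whose value is uncertain because of close copies, had a lower mean with PFOS in each of 3 diets. Its averaged fall kept an adjusted p of 0.0022 with the GC trend removed, which argues against that trend. Fewer absorptive enterocytes would lower their markers by about as much, yet against the enterocyte score Acot1 differed by −1.06 on cellulose and −3.23 on pectin (two-sided exact permutation p = 0.029 each, 70 labelings), whereas on inulin, where that score averaged 0.20 without and −0.21 with PFOS, the −1.35 had p = 0.1 (exact permutation), the smallest of 20 labelings, and leaves this open. A single shift in the time of collection with PFOS was taken to move the clock genes the same way in the 3 diets. Their score went from 0.30 to −0.40 on inulin and from −0.35 to 0.16 on pectin, each without overlap of libraries. On cellulose it went from −0.04 to 0.29, with overlap. This argues against a single shift, although no clock list call held (lowest adjusted p = 0.33 with an estimated correlation). Collection times that differed by diet cannot be told apart from an effect of PFOS. An effect of PFOS on this gene or on a close copy could account for the pattern and stays a hypothesis found on the same data.

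A score of the 313 genes changed by pectin, set by construction to 0 in Control and 1.00 in Pectin, averaged −0.03 in PFOS, 0.08 in Inulin, 0.79 in Inulin_PFOS and 0.73 in Pectin_PFOS, with 0.82 between Inulin_PFOS and PFOS, which took no part in choosing the genes (two-sided exact permutation p = 0.029, 35 labelings). Exchanged labels of single libraries between Inulin and Inulin_PFOS are argued against by the highest Inulin score of 0.22 beside the lowest Inulin_PFOS score of 0.64. An exchange of the whole groups would give the same separation and stays open. The 200 genes with the smallest p in PFOS vs Control had the same sign on inulin in 21.5% of cases, which goes with it (exact permutation p = 0.1, the smallest of 20 labelings). Acot1 was lower with PFOS on inulin (4.85 and 1.33 CPM) as on the other diets, which goes against it. That gene was picked from an average that includes the inulin libraries, so it weighs little. Lymphoid tissue and the GC trend are argued against by the 86.6% and 103% of the score difference that remained with B and T cell scores as covariates (0.62 ± 0.13, SE) and with the trend removed. A joint effect of inulin and PFOS could account for the pattern as a hypothesis, with a difference of 0.71 between Inulin_PFOS and Inulin (exact permutation p = 0.1, the smallest of 20 labelings). The interaction of the score was 0.74 (two-sided exact permutation p = 0.04, 1400 labelings), but Control took part in choosing the genes. Neither cage nor batch entered the model, and anything else shared by the libraries of a group cannot be told apart from a joint effect.

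Other splits of the same libraries showed how often chance gives as many genes. For Pectin_PFOS vs Pectin 1 of 35 splits, the real one, reached its 3277 genes (highest other 0). For Pectin_PFOS vs PFOS and Inulin_PFOS vs PFOS it was 1 of 35 each (2526, highest other 4, and 416, highest other 177), and for the averaged effect 1 of 100 (25, highest other 7). A chance result is argued against there. It is not excluded for Pectin vs Control, where 2 of 35 splits reached 313 genes and the split that exchanged Control 4 and Pectin 4 called 511. The 10 splits of Inulin_PFOS vs Inulin (1 of 10, 25 genes, highest other 0) are too few to decide. Where no gene was called, every split reaches that count by construction (35 of 35 for PFOS vs Control and for Inulin vs Control, 100 of 100 for each interaction), which decides nothing. There, a split with Control 1 on the side of Inulin called 849 genes and a split of the interaction with pectin 4712. A structure of the samples other than their groups may give such counts, as may a real contrast left in place by the split, and neither was tested. The highest others for PFOS vs Control and the interaction with inulin were 1 and 32.

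Dixon's Q test flags about 1 in 20 sets of normally distributed values, and CPM values need not be normal. It found a library far from the other 3 of its group for 34 of 398 pairs of a named gene and a group (8.54%). PFOS 4 had 7 of these, Pectin 4 had 5 and Pectin_PFOS 1 had 5. Control 2 had 14356 detected genes against 14797 to 14838 in the other Control libraries. PFOS 4 was high in Aadac (23.2 CPM), Ubd (25), Adamts5 (6.37), Ace (675), Gzmb (23.7) and Nkg7 (7.91) and low in Cdh19 (2.35). Pectin 4 was high in Itgam (20.1), Slc43a2 (357), Acot1 (14.8) and Srebf2 (176) and low in Dcn (130). Pectin_PFOS 1 was high in Pdk4 (23.9), Angptl4 (226) and Ghr (16.1) and low in Col3a1 (15.7) and Pigr (2350). In Control, replicate 1 was low in Reep5 (16.2) and Duox2 (37.6) and high in Spdef (14.6), replicate 2 was low in Gzmb (2.07), replicate 3 was high in Ociad2 (45.6) and Gpx2 (329) and replicate 4 in Bhmt (3.65).

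Single libraries also stood apart for Duoxa2 (755 CPM) and Muc2 (567) in Pectin 3, and for Plet1 (87.2), Saa3 (21.3) and Tac1 (56.5) in Pectin_PFOS 2. Genes with uncertain values did so as well: Lyz1 in Pectin 1 (3600) and Pectin_PFOS 3 (1500), Saa1 (142) and Saa2 (0.684) in PFOS 3, and Hbb-bs in PFOS 2 (98.8).

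Gene lists whose PFOS effect differed between inulin and cellulose, by the interaction term in camera, were defence (adjusted p = 1.4e-08), muscle (3.3e-08), Paneth cell (6.4e-08), interferon (7.2e-07), oxidative phosphorylation (2.4e-06), clock (3.4e-05), myeloid (7.7e-05) and fibroblast (9.9e-05). Goblet cell (0.00049), PPAR-alpha (5e-04), nerve (0.0084), inflammation (0.014), immediate early (0.014), drug metabolism (0.026), ketone body (0.042) and proliferation (0.047) lists followed. Between pectin and cellulose they were enterocyte (5.2e-14), cholesterol synthesis (4.1e-06), fibroblast (5.9e-06), interferon (9.6e-05), lipid absorption, mitochondrially encoded and red blood cell (0.0032 each) and stress response (0.0037). Proliferation and myeloid (0.012 each), Wnt (0.017), tight junction (0.034) and B cell (0.049) lists completed them. None of these 29 calls held with an estimated correlation, the lowest being adjusted p = 0.061 for the enterocyte markers. With inulin, omission of a library ended the calls of proliferation (adjusted p up to 0.52 in camera), drug metabolism (0.28), nerve (0.16), ketone body (0.15), immediate early (0.083) and inflammation lists (0.06). With pectin it ended those of B cell (0.52), lipid absorption and Wnt (0.16 each), tight junction (0.14), proliferation (0.13), myeloid (0.097) and mitochondrially encoded lists (0.068).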

How the results depend on the processing

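The settings with the GC trend removed and with library totals alone, and the list tests without single libraries, were chosen after the results had been seen. So was the omission of Pectin_PFOS replicate 1 from comparisons it is no part of, and the others were planned. Of 258 results for named genes 216 passed, and 81 of those kept their side of the threshold in every planned setting other than an omitted library, 68 with these included. No passing gene changed direction. Size factors of DESeq2 kept 209 of the 216 calls, no filter 172, the DESeq2 Wald test 216, a replicate block 192 or 170, a surrogate variable 196 and removal of the GC trend 198, whereas limma on unfiltered TPM kept 103. With the GC trend removed the share of higher genes went from 51.8% to 67.7% in Pectin vs Control, from 68% to 78.9% in the averaged effect and from 48% to 56.5% in Pectin_PFOS vs PFOS, where most called genes were then higher rather than lower (1684 and 1296). The numbers in the labels do not pair samples across groups (correlations of residuals from −0.26 to 0.30, 0 comparisons paired), so a replicate block was run only as an alternative. It moved counts both ways, with 3861 and 3544 genes for Pectin_PFOS vs Pectin, and the cause was not tested. With few libraries per group, small changes were often missed: of 100 simulated 2-fold changes 34 were recovered for PFOS vs Control and 6 for the interaction with inulin.

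Counts of changed genes moved by more than 1.5 times in the following settings, and the cause was not tested. PFOS vs Control had 0 genes, but 1 by the DESeq2 Wald test and 7 by limma on unfiltered TPM. Inulin vs Control had 0, but 783 by the Wald test. Pectin vs Control (313) gave 167 with no filter, 857 by the Wald test, 48 with the compared groups alone, 206 with a replicate block by the number in the title, 88, 87 and 26 by limma on log2(TPM + 1), log2(TPM + 0.1) and unfiltered TPM, and 126 by library totals alone. Inulin_PFOS vs Inulin (25) gave 497 by the Wald test, 0 with the compared groups alone, 41 with the title's number as a replicate block, 11, 14 and 10 by these limma settings, 81 with a surrogate variable and 68 with the GC trend removed. Pectin_PFOS vs Pectin (3277) gave 1410, 1621 and 722 by limma and 2072 with a surrogate variable. Inulin_PFOS vs PFOS (416) gave 1110 by the Wald test, 1629 with the compared groups alone, 252 with the title's replicate block, 2623, 2282 and 2290 by limma, 638 with the GC trend removed and 999 by library totals alone. Pectin_PFOS vs PFOS (2526) gave 3829 by library totals alone. The interactions (0 each) gave 659 with inulin and 135 with pectin by the Wald test. The averaged effect (25) gave 214 by the Wald test, 14 and 12 with a replicate block, 9, 9 and 6 by limma, 64 with a surrogate variable and 15 by library totals alone.

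Omitting single libraries gave 0 to 0 genes for PFOS vs Control, 0 to 794 for Inulin vs Control, 51 to 530 for Pectin vs Control, 2 to 147 for Inulin_PFOS vs Inulin and 1360 to 3336 for Pectin_PFOS vs Pectin. The ranges were 73 to 528 for Inulin_PFOS vs PFOS, 1265 to 2478 for Pectin_PFOS vs PFOS, 0 to 767 and 0 to 4 for the interactions with inulin and pectin, and 8 to 42 for the averaged effect. Part of this follows from fewer samples, and otherwise the cause was not tested.

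Only genes that did not pass changed direction, and the cause was not tested. For PFOS vs Control, Cpt1a (−0.10) turned to 0.15 in each limma setting and ranged from −0.23 to 0.14 with single libraries omitted. Pdk4 (0.42) ranged from −0.17 to 0.71. Angptl4 (−0.18) turned to 0.12, 0.13 and 0.12 by limma and ranged from −0.32 to 0.0168. For Pectin_PFOS vs Pectin, Cpt1a (0.06) turned to −0.0184 and −0.0198 with the replicate blocks and −0.19 with a surrogate variable, and ranged from −0.28 to 0.34. For Pectin_PFOS vs PFOS, Cpt1a (−0.10) ranged from −0.44 to 0.0800, and Angptl4 (0.39) turned to −0.27, −0.28 and −0.27 by limma and ranged from −0.27 to 0.59. For the interaction with pectin, Cpt1a (0.15) turned to −0.0558, −0.0565 and −0.0558 by limma and ranged from −0.18 to 0.41.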

Other observations

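Several single genes rose with fermentable fibre in exposed mice, and were chosen for this paragraph after their values had been seen. Plet1, a surface protein of epithelial cells, rose in Inulin_PFOS vs PFOS by 6.60 ± 1.20 on the log2 scale (adjusted p = 0.00754) and in Pectin_PFOS vs PFOS by 6.08 ± 1.16 (adjusted p = 0.00376). The galactosyltransferase gene B3galt5 rose by 5.87 ± 1.19 and 4.54 ± 1.10 (adjusted p = 0.0137 and 0.0118). Tac1, the precursor of substance P, rose by 3.76 ± 0.71 and 2.97 ± 0.68 (adjusted p = 0.0092 and 0.00824), and the gut hormone gene Pyy by 1.24 ± 0.28 and 1.19 ± 0.26 (adjusted p = 0.0223 and 0.00705). Cck rose in Pectin_PFOS vs PFOS (1.54 ± 0.30, adjusted p = 0.00383). Pectin_PFOS 2 stood high in Plet1 and Tac1, which without it rose by 3.87 and 1.96 with pectin and still passed. With inulin, B3galt5 lost its call without PFOS 1, PFOS 2 or Inulin_PFOS 1 (up to 0.0689), Tac1 without PFOS 2 (0.0552) and Pyy without PFOS 2, PFOS 3, Inulin_PFOS 1 or Inulin_PFOS 3 (up to 0.172).

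A few clock genes passed in single comparisons, while the list of 17 held in none with an estimated correlation (adjusted p = 0.19 in Inulin_PFOS vs PFOS and 0.33 in Inulin_PFOS vs Inulin). The clock score averaged −0.04 ± 0.22 in Control, 0.29 ± 0.43 in PFOS, 0.30 ± 0.31 in Inulin, −0.40 ± 0.25 in Inulin_PFOS, −0.35 ± 0.07 in Pectin and 0.16 ± 0.22 in Pectin_PFOS (SD). In Inulin_PFOS vs PFOS the output factor gene Hlf fell by 1.57 on the log2 scale (SE 0.36, adjusted p = 0.0234) and Per2, a repressor of the clock, by 1.10 (SE 0.27, adjusted p = 0.0313), while Nfil3, which opposes Hlf, rose (1.26 ± 0.32, adjusted p = 0.0375). Cry2, another repressor, fell in Pectin vs Control (−1.06 ± 0.27, adjusted p = 0.0462) and rose in Pectin_PFOS vs Pectin (1.17 ± 0.27, adjusted p = 0.00843), comparisons that share the Pectin libraries. Hlf lost its call without PFOS 2 or any 1 Inulin_PFOS library (up to 0.0938), Per2 without PFOS 1, 2 or 3 or Inulin_PFOS 1 or 3 (up to 0.174) and Nfil3 without PFOS 1, 2 or 3 or Inulin_PFOS 2 or 3 (up to 0.181). The fall of Cry2 with pectin was lost without any 1 Pectin library or Control 1, 2 or 3 (up to 0.142).

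Signs of the fold changes were also compared between comparisons that share libraries. The 200 genes with the smallest p in PFOS vs Control had the opposite sign in 92% of cases in Inulin_PFOS vs PFOS, which shares the PFOS libraries. In 20 simulations without any change that share was 87.5% to 95.5%, and it was 54.5% to 77% with the PFOS libraries divided between the comparisons. In Pectin_PFOS vs PFOS it was 49%, against 90.5% to 97% in simulations and 28.5% to 43% with divided libraries.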
